A study of Homo sapiens with 6 samples.

How the data were processed

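RNA was measured on 6 arrays from U87-2M1 cells, a subline of the U87 human glioma line that was recovered for its invasiveness after a lung metastasis assay in animals and grown again in culture. Per the labels, passage 4 cells were kept in hypoxia and transduced with a baculoviral vector, an insect virus vector used to carry genes into mammalian cells. The vector carried either a control decoy or a decoy for miR-10b, a decoy being a transcript meant to bind a microRNA and keep it from its targets. There were 3 arrays per group, and the group and replicate number of each array came from its title. Total RNA was extracted with TRIzol and biotin-labelled cRNA was made from 0.25 µg of it, per the labels' protocols. The labels do not say that the replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

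The deposited values are linear signal intensities, one for each of 54675 probe sets per array, and MAS5 is the tool named in the submitters' processing notes. The MAS5 version and scaling target are not given in the sources used here, and detection calls were not used here. The deposited intensities did not lie on a fully common scale. The mean signal after trimming 2% at each end was 192 on control replicate 3 and lay between 155 and 163 on the other 5 arrays. The number of arrays limits the precision of every value.

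Of the probe sets, 41097 carried 1 gene symbol in the platform annotation, 1801 carried several and 11777 carried none. Probe sets with several symbols or none were not used to name a gene, and 62 control probe sets stayed out of the gene tests, which left 41091 probe sets. Of these, 41037 were matched by Entrez identifier to a RefSeq gene table (assembly GRCh38.p14), and 0 symbols needed an update. That table served only for names and for which genes neighbour each other, and no coordinates are given because no genome build applies to the array values.

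Signals were turned into log2(signal + 7), the offset being set by a fixed rule from the median of all deposited values. Fold changes on this scale understate the change of dim genes. The probe set with the highest mean stood for each of 19775 genes, and genes under the 30th percentile of mean signal, which lay at a signal of 14.2, were left out, leaving 13842. The groups were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over the 13842 genes and a threshold of 0.05. eBayes drew each gene's variance toward that of genes of like signal, with 158 prior against 4 residual degrees of freedom. Very small p-values therefore rest mostly on variance shared across genes. The prior was 7.68 after quantile normalization, 4.43 without the intensity trend and infinite in several other settings. No further normalization was applied, a choice fixed before the values were seen on the assumption that MAS5 signals are scaled between arrays, which the brightness of control replicate 3 does not bear out. Total counts with 2 other scalings are therefore given beside it. List counts are given after quantile normalization, and after centring for some lists.

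All 23 gene lists and 8 lists of cell type markers were fixed before the data were examined. Each gene list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 23 lists, with an estimated correlation and limma's fry beside it. The genes named were also chosen by a rule fixed then. It took the 12 largest rises and 12 largest falls among genes past the threshold whose 3 miR-10b decoy arrays all lay on one side of all 3 control arrays, up to 4 members of each list with the smallest p, and 7 genes whatever their values (HOXD10, KLF4, NF1, BCL2L11, CDKN1A, TFAP2C and GAPDH). Another gene fixed then is not reported here. Other list members and 8 further lists named in the text were chosen after their values were seen. Where every array of a group lay under the filter level, the fold is given as a bound, the brighter group against the filter level.

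The alternatives tried were quantile normalization, centring on the array median, 2 other offsets, 2 other filters, the mean of all probe sets of a gene, no intensity trend, the replicate number as a block, a fold threshold, every probe set by itself, and each array left out in turn. Per-gene variances without moderation, quantile normalization without control replicate 3, and quantile normalization with an estimated correlation were added after the data were seen. On simulated data with 200 changed genes among 13842, the comparison recovered 50.8% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 92.4% of those changed 3-fold, and 6.63% of its calls were false. The G2/M list was also lowered there and left out of that last share. Noise was drawn gene by gene around the array effects, with no shift between the groups in other genes. These shares therefore do not cover genes that vary together or a scale difference between groups. Far fewer genes were changed there than the 3615 that passed in the data, which makes the adjusted cutoff stricter in the simulation. The shares thus do not carry over to the data as they stand. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.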

Results

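Gene expression was compared between U87-2M1 glioma cells carrying a miR-10b decoy and the same cells carrying a control decoy, with 3 arrays each. The comparison asks which transcripts differ with a decoy meant to bind miR-10b, a microRNA abundant in glioma and linked to invasion in other tumours. Whether the decoy bound miR-10b was not measured here. Arrays of 1 group correlated with r between 0.985 and 0.988 over the tested genes, and arrays of different groups with r between 0.967 and 0.974. The median log2 difference over all tested genes was -0.14, and was -0.02 after quantile normalization. Log2 changes below are therefore given relative to the median of all genes, with the standard error (SE) and adjusted p of limma's test of the unshifted difference. The words higher and lower are used for genes past that test.

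The 12 largest rises with the miR-10b decoy came from genes of different kinds. SPRR2B, a cornified envelope protein of squamous epithelia, had a signal of 61.0 ± 19.6 in controls and 551 ± 46.7 with the decoy (SD, n = 3), a relative log2 change of 3.21 (SE 0.16, adjusted p = 6.1e-41). HSPA6, a stress-inducible heat shock protein, rose by 2.99 (SE 0.17) and IL24, a cytokine of the interleukin-10 family, by 2.69 (SE 0.14). The interleukin-36 receptor antagonist IL36RN rose by 2.66 (SE 0.13), from 210 ± 25.5 to 1241 ± 128 (SD, n = 3). MEGF6 and the antisense transcript ATP13A4-AS1 were also among them, but 2 of the 3 control arrays of each lay under the filter level, so no exact size is given. Further rises were LINC00304 at 2.47, the serpin SERPINB4 at 2.46 and the incretin receptor GIPR at 2.43 (SERPINB4 and GIPR each with 1 control array under the filter level), the iron-binding lipocalin LCN2 at 2.40 and the antisense transcript PAX8-AS1 at 2.30. LOC101927798 was at least 4.24-fold higher, its control arrays all lying under the filter level (3.81 ± 3.93 against 83.8 ± 14.5 with the decoy, SD, n = 3). The SPRR2B, LOC101927798 and HPGD probe sets carry a suffix that marks possible cross-hybridisation. Some genes named below rest on such probe sets too, among them GDF15, CDT1, TUBB3, CASP6, IDI1, CDKN2A, SPRR3 and SERPINB3. Of the 3 PAX8-AS1 probe sets, 1 went the other way.

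Among the falls were HPGD, which degrades prostaglandins, at -1.80 (SE 0.15, adjusted p = 7.5e-24), and GABRA2, a subunit of the GABA-A receptor, at -1.78 (SE 0.15). GABRA2 went from 356 ± 40.6 to 88.5 ± 5.76 (SD, n = 3). The netrin receptor DCC changed by -1.61 (SE 0.18; its call ended with the mean of all probe sets, adjusted p = 0.131), TNFRSF11B (osteoprotegerin) by -1.53 and VWA5A by -1.50. PLEKHA6, with 1 decoy array under the filter level, and TMEM255A changed by -1.57 and -1.51. The neuronal membrane protein SLITRK6 was also lower, with 2 of its 3 decoy arrays under the filter level. Bounds apply where all decoy arrays lay under the filter level: CAPN13, a calpain protease, was at least 2.33-fold lower, the potassium channel KCNH2 at least 2.66-fold, NLRX1 at least 2.06-fold and the homeobox gene BARX2 at least 2.04-fold. For each of these 24 leading genes the 3 decoy arrays lay beyond all 3 control arrays, as the rule required, and chance alone gives such separation to 10% of genes. Without moderation the calls of LINC00304, GIPR, DCC, PLEKHA6, NLRX1 and BARX2 ended (adjusted p from 0.065 to 0.090).

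Of 13842 genes, 3615 passed the threshold, 1078 higher and 2537 lower with the miR-10b decoy. After quantile normalization 2299 were higher and 2390 lower, and after centring on the array median 2854 were higher and 1728 lower, so the split between directions rested on the scaling. Without control replicate 3, the brightest array, 1909 were higher and 2067 lower, and without miR-10b decoy replicate 3 the counts were 712 and 1466, and without miR-10b decoy replicate 1 they were 815 and 1681. With per-gene variances and no moderation, an alternative added later, 509 genes passed, and 42 of the 102 named genes that had passed still did. Lower there were 7 genes of the G2/M list, 4 of the matrix list, 2 of the G1/S list, 1 of the hypoxia list and 0 of the cholesterol list. Higher there were 2 p53 targets, 1 heat shock protein and 0 reported targets of miR-10b or miR-10a. With the mean of all probe sets the calls of ACTA2, AGO4, APAF1, ATF3, BCAN, DCC, DROSHA, FOSL2, HOXB3, HOXD9, IDI1, IFIT2, IL1A, KLF2, LSS, MDM2, NES, OAS3, PCDH10, PDGFRA, PLK3, STAT3, TGFBR2 and TNRC6C ended, and without the intensity trend those of BIRC2, CASP6, CCN1, CXCL1, DNAJB1, DROSHA, HOXB3, HOXD9, IFIT2, LSS, MMP1, NES, PAX6, SPP1 and TUBB3. The actin 3'/5' signal ratio, a sign of RNA integrity, was 5.73 ± 0.47 in controls and 8.54 ± 1.77 with the decoy (SD, n = 3, exact permutation p = 0.1, the smallest this design allows), whereas that of GAPDH was 0.945 ± 0.019 and 0.943 ± 0.007.

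**Figure D1:**
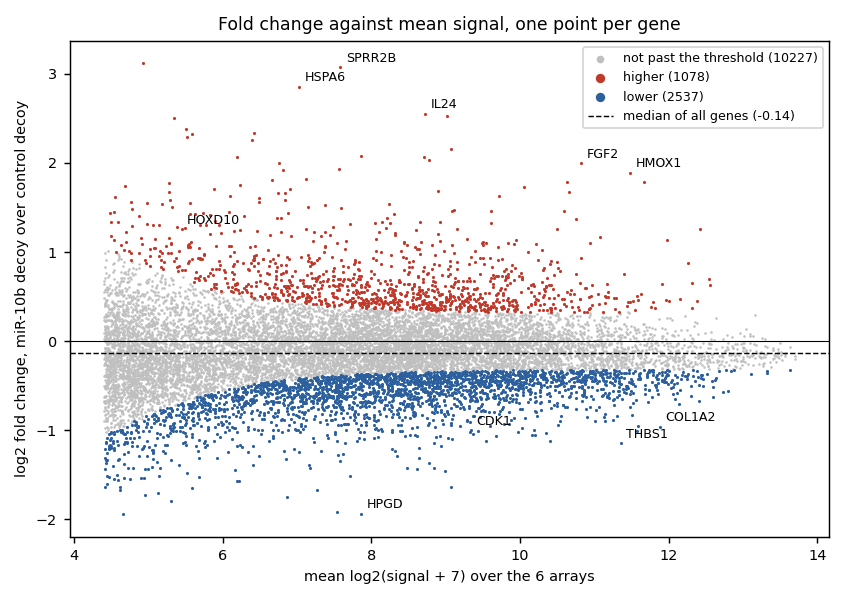
Log2 fold change of the miR-10b decoy over the control decoy against mean log2(signal + 7) for the 13842 tested genes, with genes past the threshold coloured by direction. The dashed line marks the median of all genes at -0.14, and lower genes (2537) outnumber higher ones (1078) on this scale, though not after centring on the array median (2854 higher, 1728 lower).

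Few reported targets of miR-10b and its sister miR-10a passed. Among 22 tested members 3 were higher, 19 did not pass and 0 were lower, with 2 higher when adjusted over the list alone. The count moved with the scaling, to 5 higher after quantile normalization, 10 after centring on the array median and 6 without control replicate 3, with 0 lower in each. HOXD10, the homeobox gene first reported as a miR-10b target in breast cancer cells, rose from 21.7 ± 5.96 to 60.9 ± 7.81 (SD, n = 3), a relative log2 change of 1.39 (SE 0.27, adjusted p = 1.2e-04). PAX6, a neural transcription factor, was higher at 0.63 and HOXB3 at 0.60, but the other HOXB3 probe set had an unshifted log2 change of -0.75. The PAX6 arrays of the groups overlapped, and its call ended with no filter (adjusted p = 0.156), without the intensity trend and when control replicate 1 (adjusted p = 0.217) or 2 or miR-10b decoy replicate 2 or 3 was left out. That of HOXB3 ended without the trend and without control replicate 2 (adjusted p = 0.054) or miR-10b decoy replicate 3 (adjusted p = 0.092). The list median was 0.22 above that of all genes (camera adjusted p = 0.028), and the call was lost, at adjusted p = 0.932 with an estimated correlation. The other targets fixed by name did not pass in the values as deposited: KLF4 had 0.36 (adjusted p = 0.256), BCL2L11, which encodes BIM, 0.47 (adjusted p = 0.144), CDKN1A, which encodes p21, 0.30 (adjusted p = 0.377) and TFAP2C -0.08 (adjusted p = 0.637). The only NF1 probe set that carried 1 symbol stood near background, at 19.3 ± 7.04 and 18.3 ± 5.11 (SD, n = 3), so it says little about the gene. CDKN2A, which encodes p16, had -0.76 (adjusted p = 0.051), passing without the trend (adjusted p = 0.029). Under quantile normalization BCL2L11 (adjusted p = 0.019) and CDKN1A (adjusted p = 0.00104) passed upward, and KLF4 did after centring (adjusted p = 0.024), though 4 of the 6 BCL2L11 probe sets had the opposite sign. The list's call also ended with the mean of all probe sets (adjusted p = 0.206), with a filter at the 50th percentile (adjusted p = 0.055) and without miR-10b decoy replicate 3 (adjusted p = 0.059). Without moderation the call of HOXD10 ended (adjusted p = 0.057), and 0 members of the list passed. The other HOXD10 probe sets lay under the filter level, with unshifted log2 changes of -0.09 and -0.14. The reference gene GAPDH had a relative change of -0.04 (adjusted p = 0.316).

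Next to HOXD10, its neighbour HOXD9 was higher (1.15, SE 0.37, adjusted p = 0.031, with 2 of 3 control arrays under the filter level), from 13.4 ± 10.6 to 31.2 ± 5.99 (SD, n = 3). These were the 2 higher of 7 tested HOXD cluster genes, with the same counts when adjusted over the list alone and 3 higher after quantile normalization, and the list missed the threshold (camera adjusted p = 0.061). It passed with no filter (adjusted p = 0.033), without the intensity trend (adjusted p = 0.023), without control replicate 2 (adjusted p = 0.027) and without miR-10b decoy replicate 1 (adjusted p = 0.041), all at the preset correlation, against adjusted p = 0.932 with an estimated correlation. HOXD11 and HOXD13 had values of 0.84 and 0.78 that did not pass, with 1 and 2 of their 3 control arrays under the filter level. HOXD11 passed after quantile normalization (adjusted p = 0.045) and HOXD13 without control replicate 3 (adjusted p = 0.026). The HOXD9 arrays of the groups overlapped, and its call ended when any array but control replicate 2 was left out (adjusted p from 0.052 to 0.130), as well as with the mean of all probe sets, no filter or no intensity trend. In the microRNA pathway, TNRC6B and TNRC6C, scaffold proteins of the silencing complex, were higher at 0.93 and 0.79, the Argonaute AGO4 at 0.63, and the processing enzyme DROSHA was lower at -0.20. Among its 12 tested members 3 were higher and 1 lower, also when adjusted over the list alone, against 6 and 1 after quantile normalization and 8 and 0 after centring. The list missed the threshold (camera adjusted p = 0.067), but passed after centring (adjusted p = 0.0496), with no filter (adjusted p = 0.033), without the trend (adjusted p = 0.035) and without control replicate 3 (adjusted p = 0.048), all at the preset correlation, against adjusted p = 0.932 with an estimated correlation. The DROSHA call ended after centring (adjusted p = 0.094), with no filter, the mean of all probe sets or no trend, and when any array but control replicate 1 was left out (adjusted p from 0.053 to 0.180). The TNRC6C call ended with no filter (adjusted p = 0.093) and without control replicate 1 or miR-10b decoy replicate 1 or 2. That of AGO4, whose second probe set went the other way, ended without miR-10b decoy replicate 3.

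Cell cycle genes were lower with the miR-10b decoy. CDK1, the kinase that drives entry into mitosis, fell from 910 ± 106 to 451 ± 43.9 (SD, n = 3), a relative log2 change of -0.86 (SE 0.13, adjusted p = 3.1e-10). The spindle protein DLGAP5 changed by -0.93, the mitotic kinesin KIF11 by -0.85 and cyclin A2 (CCNA2) by -0.84. Among 25 tested genes of G2/M and mitosis 24 were lower and 0 higher, in the same numbers when adjusted over the list alone, after quantile normalization and without control replicate 3. The list median lay 0.59 below that of all genes (camera adjusted p = 4.1e-16, adjusted p = 0.932 with an estimated correlation). Fry, which tests the list against no change and not against other genes, gave adjusted p = 0.027. Of 25 genes of G1/S and DNA replication 18 were lower and 0 higher, or 21 lower when adjusted over the list alone (camera adjusted p = 2.1e-06, adjusted p = 0.932 with an estimated correlation). The lower genes numbered 18 after quantile normalization, 13 after centring and 16 without control replicate 3, with 0 higher in each. The replication licensing genes CDT1 (-0.75), MCM3 (-0.69) and CDC6 (-0.69) and thymidylate synthase (TYMS, -0.65) had the smallest p. The actin 3'/5' ratio given above moved with the same arrays.

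Among p53 targets, the stress cytokine GDF15 rose from 901 ± 133 to 2881 ± 224 (SD, n = 3), a relative log2 change of 1.82 (SE 0.13). MDM2, which degrades p53, and the kinase PLK3 were each higher at 0.77, though each has a probe set of the opposite sign, and cyclin G1 (CCNG1) was lower at -0.44. Of 20 tested members 7 were higher and 3 lower, 8 and 4 when adjusted over the list alone and 9 and 3 after quantile normalization (camera adjusted p = 0.011, adjusted p = 0.932 with an estimated correlation). After centring on the array median 10 were higher and 1 lower. The p53 list's call ended with the mean of all probe sets (adjusted p = 0.162). Apoptosis genes did not move as lists. The caspase activator APAF1 (-0.68), CASP9 (-0.57) and CASP6 (-0.29) were among 6 lower of 18 pro-apoptotic genes, and HRK, a BH3-only protein, was the 1 higher, at 1.29 with 2 of 3 control arrays under the filter level (camera adjusted p = 0.786). Adjusted over the list alone the counts were 3 higher and 6 lower. After quantile normalization 4 were higher and 6 lower, and after centring on the array median the balance turned to 4 higher and 2 lower, CASP6 no longer passing (adjusted p = 0.091). The CASP6 call also ended without control replicate 1 or miR-10b decoy replicate 2 or 3. Of 10 anti-apoptotic genes, BIRC5 (survivin, -0.62) and BIRC2 (-0.42) were lower and 0 were higher, also when adjusted over the list alone, with 2 higher and 2 lower after quantile normalization (camera adjusted p = 0.522). BCL2 had -0.53 (adjusted p = 0.061), passing without the trend (adjusted p = 0.027), with another probe set at an unshifted 0.57, and BIRC6 had -0.11 (adjusted p = 0.165).

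Genes of the extracellular matrix were mostly lower. THBS1, a matrix glycoprotein that inhibits angiogenesis, fell from 3908 ± 330 to 1763 ± 166 (SD, n = 3), a relative log2 change of -1.01 (SE 0.13, adjusted p = 8.8e-14), with 1 of its 7 probe sets going the other way. CCN2 (connective tissue growth factor), COL1A2 and SPARC changed by -0.87, -0.82 and -0.64. Among 25 collagens and matrix proteins 14 were lower and 2 higher, 15 and 2 when adjusted over the list alone and 14 and 2 after quantile normalization (camera adjusted p = 2.2e-04, adjusted p = 0.932 with an estimated correlation). The 2 higher were the proteoglycans DCN and LUM, at 0.84 and 0.83. The invasion and matrix proteolysis list split, with 4 higher and 11 lower of 28, also when adjusted over the list alone (camera adjusted p = 0.522). After quantile normalization 8 of the list were higher and 11 lower, and after centring 9 and 10. Its collagenase MMP1 and membrane protease MMP14 were higher at 0.64 and 0.74, while TIMP3, an inhibitor of metalloproteases, and the sheddase ADAM10 were lower at -1.34 and -0.41.

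Regulators of epithelial-mesenchymal transition went both ways. SNAI2, a transcriptional repressor, was higher at 1.04 (SE 0.13), while TWIST1 was lower at -0.47 (SE 0.13). The ligand TGFB2 (-0.68) and its receptor TGFBR2 (-0.45) were also lower, so that of 15 tested members 2 were higher and 3 lower, also when adjusted over the list alone, and 3 and 3 after quantile normalization (camera adjusted p = 0.988). In the TGF-beta response 2 of 19 were higher and 6 lower, or 2 and 7 when adjusted over the list alone and 3 and 5 after quantile normalization (camera adjusted p = 0.456). The pseudoreceptor BAMBI was higher at 1.10, and smooth muscle actin (ACTA2) and CCN1 were lower at -0.51 and -0.44.

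Mesenchymal glioblastoma markers did not shift as a list. Of 22 tested, 1 was higher and 3 lower, also when adjusted over the list alone, against 6 and 4 after quantile normalization (camera adjusted p = 0.625). FOSL2, an AP-1 subunit, was the higher one at 0.75, and besides THBS1 the lower ones were STAT3 (-0.37) and SPP1, osteopontin (-0.26). FOSL2 and STAT3 each have probe sets of the opposite sign, and the SPP1 call ended without miR-10b decoy replicate 1 (adjusted p = 0.113) or 3 and without the trend. Among proneural and neural stem cell markers, the growth factor receptor PDGFRA rose from 92.4 ± 18.3 to 277 ± 31.4 (SD, n = 3), a relative log2 change of 1.66 (SE 0.16), and brevican (BCAN) was higher at 1.20 with another probe set going the other way. Nestin (NES, -0.33) and TUBB3 (-0.20) were lower, making 2 higher and 2 lower of 10, also when adjusted over the list alone, and 3 and 2 after quantile normalization (camera adjusted p = 0.265). The TUBB3 call ended with no filter, no trend and without control replicate 2 or any 1 of the miR-10b decoy arrays (adjusted p up to 0.191), and that of NES without miR-10b decoy replicate 3 (adjusted p = 0.101), without the trend or with the mean of all probe sets. The call of PDGFRA ended with the mean of all probe sets (adjusted p = 0.507). The proneural median lay 0.10 below that of all genes while its mean and camera's direction were upward, and the mesenchymal, angiogenic and epithelial-mesenchymal medians lay 0.01, 0.01 and 0.04 above it while camera's direction was downward.

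FGF2, a growth factor for endothelial cells, rose from 907 ± 161 to 3619 ± 469 (SD, n = 3), a relative log2 change of 2.13 (SE 0.13, adjusted p = 2.2e-30). The endothelial ligand ANGPT1 changed by -1.07 (SE 0.17). Of 23 angiogenic factors and receptors 2 were higher and 7 lower, also when adjusted over the list alone, and 2 and 6 after quantile normalization (camera adjusted p = 0.625). THBS1 and TIMP3, both inhibitors of vessel growth, were among the lower. Hypoxia response genes were mostly lower, with both groups of cells kept in hypoxia. NDRG1 went from 2753 ± 184 to 1661 ± 287 (SD, n = 3), at -0.60 (SE 0.13), and the glycolytic regulator PFKFB4, aldolase C (ALDOC) and the adenylate kinase AK4 changed by -0.79, -0.73 and -0.63. Of 25 tested 14 were lower and 2 higher, or 18 and 2 when adjusted over the list alone (camera adjusted p = 2.5e-04, adjusted p = 0.932 with an estimated correlation). After quantile normalization 16 were lower and 2 higher, and after centring 14 and 3. The 2 higher in the values as deposited were ADM (0.59) and HK2 (0.59).

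The unfolded protein and amino acid stress list went both ways. TRIB3 (1.61), PPP1R15A (1.27), ATF3 (1.24) and the amino acid transporter subunit SLC3A2 (1.01), genes induced through ATF4 under amino acid shortage, were higher, while the endoplasmic reticulum chaperone genes HSPA5 (-0.22), SDF2L1 (-0.70) and HYOU1 (-0.51) were lower. Of 22 tested 7 were higher and 8 lower, 8 and 10 when adjusted over the list alone and 10 and 8 after quantile normalization (camera adjusted p = 0.10). Besides HSPA6, the co-chaperone DNAJB1 was higher (0.56), making 2 higher and 0 lower of 11 heat shock proteins, also when adjusted over the list alone, against 7 and 0 after quantile normalization and 4 and 0 without control replicate 3 (camera adjusted p = 0.011, adjusted p = 0.932 with an estimated correlation). The DNAJB1 call, and with it 1 of the 2 higher, ended without control replicate 2 (adjusted p = 0.090), miR-10b decoy replicate 2 (adjusted p = 0.066) or replicate 3 (adjusted p = 0.059), and without the trend. HSPB1 and CRYAB had 0.32 and -0.16 and did not pass, though HSPB1 passed upward after quantile normalization (adjusted p = 0.00373).

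Cholesterol synthesis genes were mostly lower, 7 of 13 with 1 higher, 8 and 1 when adjusted over the list alone and 6 and 1 after quantile normalization (camera adjusted p = 0.011, adjusted p = 0.932 with an estimated correlation), and the call ended with the mean of all probe sets (adjusted p = 0.077). Without moderation 0 of the 13 passed in either direction. The sterol carrier STARD4 (-0.81), MSMO1 (-0.71) and IDI1 (-0.54) were lower and lanosterol synthase (LSS, 0.68) was the higher one, with 2 of the 4 IDI1 probe sets going the other way. Immediate early genes went both ways, 6 higher and 6 lower of 20, also when adjusted over the list alone, against 8 and 4 after quantile normalization and 11 and 4 after centring (camera adjusted p = 0.067). KLF6 (1.39), ATF3 and KLF2 (0.95) were higher and EGR3 was lower (-0.99), with ATF3 and KLF6 each having 1 probe set of the opposite sign.

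Inflammatory cytokines also went both ways. CSF3, the granulocyte colony-stimulating factor, rose from 933 ± 125 to 2557 ± 79.2 (SD, n = 3), at 1.59 (SE 0.13), and the chemokine CXCL1 was higher at 0.74, while the monocyte chemokine CCL2 (-0.82) and IL1A (-0.57) were lower. The second IL1A probe set had the opposite sign. Of 22 NF-kB and inflammatory genes 5 were higher and 3 lower, also when adjusted over the list alone (camera adjusted p = 0.067). After quantile normalization 12 were higher and 3 lower and the list passed (camera adjusted p = 0.032), with adjusted p = 0.680 with an estimated correlation, and it passed without control replicate 3 (adjusted p = 0.00255). Interferon response genes were 2 higher and 4 lower of 20, also when adjusted over the list alone and after quantile normalization (camera adjusted p = 0.841), with the antiviral gene OAS3 at -1.01, USP18 and IFI6 each at -0.60 and IFIT2 at 0.91. Another IFIT2 probe set had the opposite sign, and its call ended without miR-10b decoy replicate 3 (adjusted p = 0.087), with no filter, no trend or the mean of all probe sets. Among 19 adhesion and neuronal guidance molecules 2 were higher and 5 lower, 3 and 5 when adjusted over the list alone and 4 and 5 after quantile normalization (camera adjusted p = 0.619). The ephrin receptor EPHA5 (-0.98), the protocadherins PCDH10 (-0.79) and PCDH7 (-0.44) and SEMA5A (-0.72) were lower.

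Markers of other cell types were mostly lower where they passed, as were genes past the threshold at large on this scale (2537 lower of 3615). Apart from fibroblast markers (421), the median control signals of the marker lists lay between 37.5 and 147. Of neuronal markers 3 of 5 were lower, SNAP25 at -0.82, NEFM at -0.88 and SLC17A7 at -1.19, and 2 were lower after quantile normalization. Endothelial markers had 2 of 3 lower (TEK at -0.53 and PECAM1 at -0.37), lymphocyte markers 1 of 3 (CD79A at -0.55), lung epithelium markers 1 of 7 (MUC1 at -1.11), and 0 of any of these were higher. Oligodendrocyte markers had 1 of 4 lower (MAG at -0.70, not past the test after quantile normalization), macrophage and microglia markers had 0 of 3 past the test, and the astrocyte glutamate transporter SLC1A3 was higher at 0.74, the 1 of 4 astrocyte markers to pass. Of 8 fibroblast markers DCN and LUM were higher and COL1A2 was lower.

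**Figure D2:**
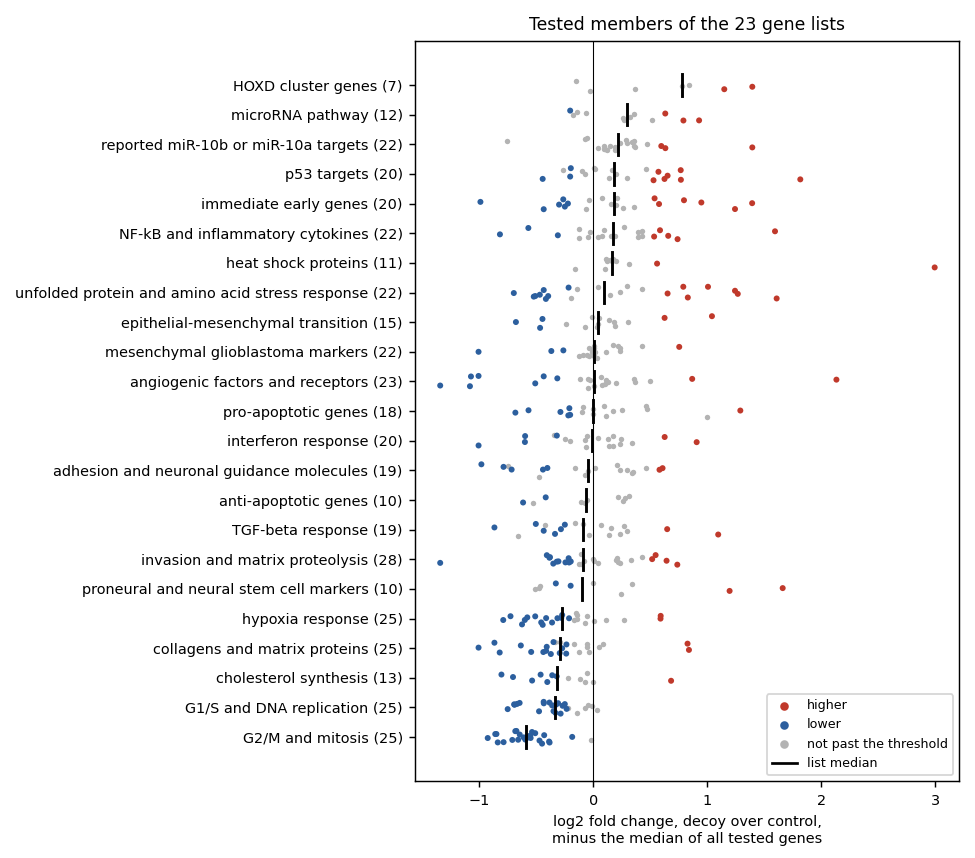
Log2 fold change of each tested member of the 23 gene lists, relative to the median of all genes, with members past the threshold coloured by direction and a bar at each list's median. The G2/M list lies lowest, 0.59 below all genes, and the HOXD cluster highest, 0.78 above them, though it missed the threshold (camera adjusted p = 0.061). The HOXD median is the value of HOXD13, with 2 of its 3 control arrays under the filter level.

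**Figure D3:**
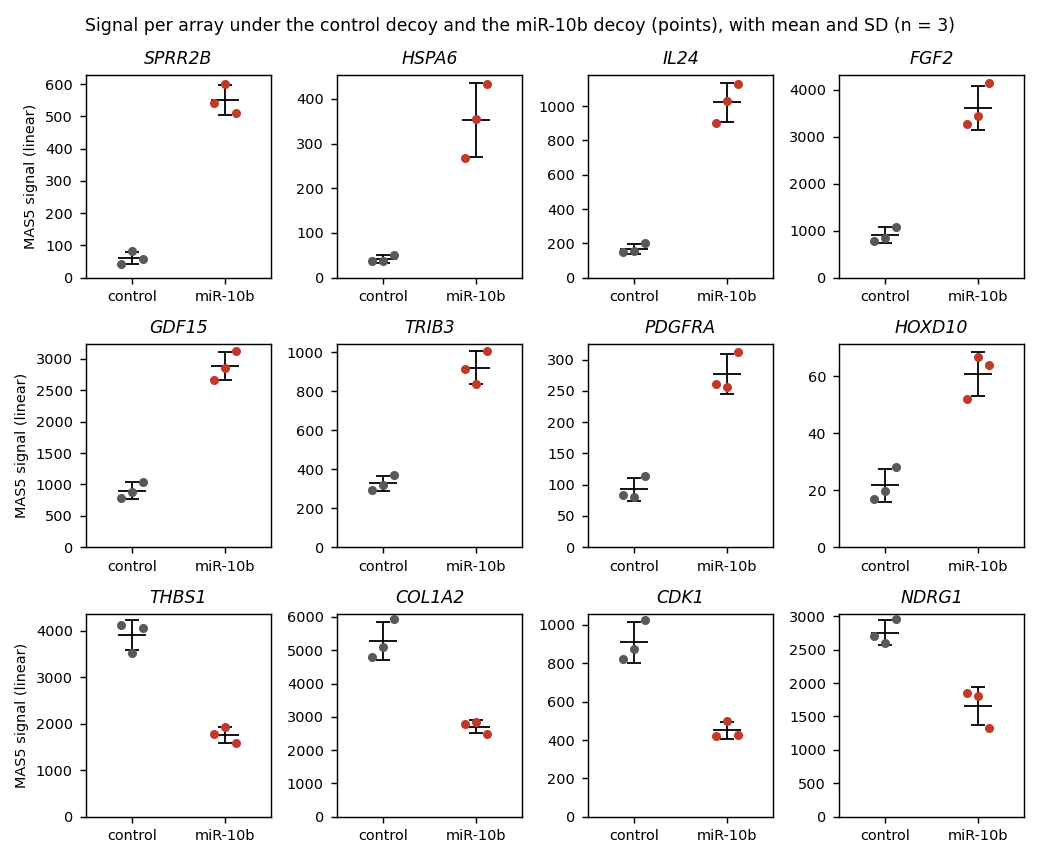
MAS5 signal of 12 named genes on each array (points), with the mean and SD of the 3 arrays per group and each axis starting at 0. In every panel the 3 decoy arrays lie beyond all 3 control arrays, higher for 8 genes from SPRR2B to HOXD10 and lower for THBS1, COL1A2, CDK1 and NDRG1.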

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

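The probe set for the 5' end of 28S ribosomal RNA, a control feature outside the gene tests, was looked at because its signal rose with the miR-10b decoy, and both tests of it were chosen after that was seen. Its signal was 3353 ± 406 in controls and 7548 ± 684 with the decoy (SD, n = 3, exact permutation p = 0.1, the smallest this design allows). That is a log2 change of 1.17, unshifted like the other log2 changes of this paragraph. Of 55 control probe sets above the filter level it was the 1 higher on all 3 decoy arrays, while 33 were lower on all 3. Array brightness is argued against, because the 18 hybridization controls had a median log2 change of -0.21 (range -0.36 to -0.06). More ribosomal RNA in the labelled sample is argued against as well, because the other 5 ribosomal RNA probe sets had a median log2 change of 0.12 and at most 0.26. Among these the probe set for the middle of 28S had 0.17. That for its 3' end stood near the filter level, at 17.8 ± 9.46 and 10.3 ± 3.44 (SD, n = 3), and says little. The rest read another ribosomal RNA. Other sources, such as how the 5' end of that RNA was copied and labelled, were not tested, nor was cross-hybridisation with a transcript of the vector, whose sequence was not used here.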

How the results depend on the processing

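The settings called added were chosen after the data were seen. Among the 102 named genes past the threshold, 38 kept their direction and their call in every alternative that tested them. HOXB3 was the 1 that turned, to an unshifted -0.15 with the mean of all its probe sets (adjusted p = 0.622). The median of all genes was -0.13 in that setting, so HOXB3 lay near it. Per-gene variance without moderation (added) ended the most calls, 60 of 102, followed by the mean of all probe sets with 23, besides HOXB3, which turned and lost its call. The 3615 genes past the threshold (1078 higher, 2537 lower) became 2387 with no filter (1624 lower), 2057 with the mean of all probe sets (554 higher, 1503 lower), 1973 without the intensity trend (634 higher, 1339 lower) and 509 without moderation (196 higher, 313 lower). A fold of at least 1.5 left 1686 (556 higher, 1130 lower), but 1486 (825 higher, 661 lower) when the fold was taken relative to the median. After quantile normalization that fold left 1441 (821 higher, 620 lower), so this balance too rested on the scaling. Testing every probe set by itself gave 6142 (1916 higher, 4226 lower) of 38229. Genes higher numbered 2299 after quantile normalization, 2854 after centring and 2169 after quantile normalization without control replicate 3 (added). Leaving out 1 array at a time gave 2178 to 3976 genes, 712 to 1909 higher and 1466 to 2570 lower. The lowest count came without miR-10b decoy replicate 3 (2178), lower genes fell to 1681 without miR-10b decoy replicate 1, and higher genes rose to 1909 without control replicate 3. With 2 arrays in a group the spread came from both groups together.

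Of 23 lists 8 passed, against 5 with the mean of all probe sets, 1 with fry, which tests each list without setting it against other genes, 0 with an estimated correlation and 0 with quantile normalization and an estimated correlation (added). Leaving out 1 array gave 7 to 10 lists. Fewer tested units or samples, or a wider variance, enter some of these changes by construction. The estimated correlations, from 0.19 to 0.71 against the preset 0.01, widen camera's test as well. After quantile normalization they ran from -0.10 to 0.33, so they moved with the scaling, and the lowest adjusted p of any list was 0.359. Otherwise the cause was not tested. With the replicate number as a block 3147 genes passed (965 higher, 2182 lower) and 2 of 102 named calls ended, those of DROSHA and TUBB3. The pairing has little in the data to rest on, since deviations of same-numbered arrays correlated at 0.036, -0.032 and -0.003 and not every array correlated best with its own number. The test of genes with miR-10 seed sites was not run. Genes with signals near the filter level of 14.2, such as HOXD9 and NF1, have the widest errors, and a change there was not detectable unless large.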

Other observations

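The gene lists in the first paragraphs and the tests of array scaling, RNA integrity and heat shock were chosen after the results were seen. Of 33 squamous differentiation genes listed 16 were tested, and 9 of these were higher and 1 lower, also after quantile normalization. Besides the leading genes SPRR2B, IL36RN, SERPINB4 and LCN2 and the cytokine IL36G, these were SPRR3 at a relative log2 change of 1.77, SERPINB3 at 1.59, the elastase inhibitor PI3 at 1.35 and involucrin (IVL) at 1.16, with the keratin KRT10 lower at -0.37. CNFN, CSTA, KRT5, S100A8, S100A9 and SPRR1A did not pass. The filter took the mean over both groups, so a dim gene could enter through the group where it was higher. IVL, for example, had a signal of 12.5 ± 9.41 in controls (SD, n = 3), under the filter level of 14.2. Of 13 listed genes of the interleukin-20 and interleukin-1 families 8 were tested. Of these 5 were higher and 1 lower, or 6 and 1 after quantile normalization, the higher including the receptor antagonist IL1RN (1.73), IL36B (1.52) and IL36G (1.25). Both lists were drawn up from leading genes and not tested for enrichment, so their counts are no independent evidence.

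Of 14 listed GABA receptor and neuronal genes, also drawn from leading genes, 8 were tested. Of these 6 were lower and 0 higher, before and after quantile normalization, including GABRB1 (-1.43) and the growth cone protein GAP43 (-1.38). Among 17 targets of the oxidative stress factor NRF2, 5 were higher and 1 lower, or 8 and 1 after quantile normalization. Heme oxygenase HMOX1 led at 2.03, and AKR1B10 was the lower one at -0.68. Of 11 histone genes tested, from 19 listed, 3 were higher (H2AC8 at 0.82, H2AC6 at 0.81 and H1-2 at 0.73), or 4 after quantile normalization. Of 27 proteasome genes 1 was higher and 2 lower, or 5 and 2 after quantile normalization. Among 40 cytosolic ribosomal protein genes 0 passed, and 5 were higher after quantile normalization. Of 16 ERK feedback and AP-1 genes 1 was higher (DUSP4) and 3 lower, or 3 and 3 after quantile normalization.

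The lower cell cycle genes were set against 3 explanations. Array scaling is argued against, because the 50 tested cell cycle genes lay 0.47 below all genes after quantile normalization (-0.47, 95% bootstrap interval -0.60 to -0.39). For RNA integrity, the cell cycle level within groups changed by 0.017 per log2 unit of the actin ratio (95% interval -0.33 to 0.36, 3 residual degrees of freedom). The group difference needs -0.92. However, the log2 ratio ran from 2.40 to 2.64 in controls and from 2.88 to 3.40 with the decoy, without overlap. Noise in the ratio over such narrow ranges flattens the slope, so RNA integrity stays open. Fewer dividing cells with the decoy stays open, since the test set against it was void. The cell cycle median lay below that of 67 proteasome and ribosomal protein genes (-0.47, interval -0.59 to -0.38), but those sit near the median of all genes, so the value repeats the one relative to all genes. A difference between cultures was not tested and stays open too.

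HSPA6 and HMOX1 may belong to a wider stress response, and the counts did not decide it. For a general heat shock response, 1 of the 10 other heat shock genes tested was higher, and 6 after quantile normalization, so the scaling keeps this open. For NRF2 activation, 4 of the 16 other targets were higher, and 7 after quantile normalization, which is neither few nor most of them.

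A copy number or clonal difference between the transduced cells might shift neighbouring genes together. The largest shift of any 50 neighbouring genes relative to all genes was 0.278 in size, downward, from CAMK2D to RAB33B. In 0.007 of 1000 shuffles of gene order some window shifted by as much, and 3 overlapping windows there passed the 95th percentile of the shuffles' largest shift (0.252), so the shift stood out from shuffled order. It stayed under the largest shuffle (0.306), the bound set beforehand for this explanation. Shuffling also breaks up neighbours regulated together, which was not tested, so a copy number difference cannot be told apart from that and stays open. For the count of genes past the threshold, 1 of the 10 splits of the 6 arrays, the real one, gave 3615 genes and the highest of the others gave 0. With 10 splits no share under 0.05 can be reached.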
